A study of Rattus norvegicus with 2 samples.

How the data were processed

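Total RNA from dish cultures of IEC6 cells, 1 sample per group, was amplified, labelled with Cy3 and hybridised to Agilent arrays, per the labels' protocols. Each sample's group was taken from its treatment label: water for 60 min, or Na2S3 for 60 min. Both arrays lay on 1 slide and were scanned on 1 day, per the file headers, so slide and day do not separate the groups.

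The scanner files hold spot intensity values on a linear scale, with 1 channel, from Agilent Feature Extraction version 10.7.1.1, per the file headers, while the submitters' processing notes name version 9.5.1.1. Their processed signal is background-subtracted and spatially detrended within the array by that software, per the file headers, and was not normalized between arrays. The deposited value table holds linear intensity values as well. Its normalization is not given in the sources used here, but its columns share a median of 19.3, their sorted values differ by at most 0.362, and each follows its own array's processed signal (Pearson r 0.99997 on the log2 scale over probes), which is what quantile normalization of the pair would give. Direction and scale of that table are therefore known, and the tool that made it is not.

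The arrays carry 58717 non-control spots of 45598 probes, 1350 of them spotted 10 times. Gene names came from the file's RefSeq accession through a table of the GRCr8 assembly, without version numbers, for 21109 probes. A further 14743 probes kept the gene name in the file, and 9746 have only an accession or transcript identifier and were left out of gene counts. Coordinates are those of the files, which name rn4. Exon or UTR positions were not analysed here.

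Spots flagged as outliers were left out (448 on the control array, 390 on the Na2S3 array), and 0 spots were saturated. The log2 processed signal was averaged over the spots of a probe, and each array's 75th percentile over non-control probes (413 and 478 intensity units) was subtracted, which removed a shift of 0.21. The 7 spike-in control probes above background gave a shift of 0.16, with a range of 0.09 to 0.32. A probe was well above background on an array when more than 50% of its spots carried the software's flag for that. A gene's value is its brightest probe among those well above background on both arrays, and the ratio is always the Na2S3 array over the control array. The median log2 ratio of measured genes was -0.04 and their SD 0.34. For a gene above background on 1 array alone, the bound is the bright array's value over the higher of the dim probe's own value and the lowest value among probes well above background on the dim array. A gene counted as not above background only when all its probes were.

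With 1 array per group there is no test across genes, and the number of arrays limits the precision. Genes were counted by a fixed rule of size, a log2 ratio of 1 or more either way. Each of 23 gene lists has its median log2 ratio and the percentile of that median among 10000 random lists of the same size matched on mean signal in 20 bins, as a description of these arrays. The lists cover NRF2, HSF1, immediate early, metal response, ATF4, unfolded protein response, p53, NF-kB, hypoxia, glycolysis, sterol, sulfur, other antioxidant, junction, intestinal, fibroblast, immune and endothelial, S phase, G2 and M phase, TGF-beta and BMP, proteasome, ribosomal and housekeeping genes. The groups, lists, rule of size, naming rule and processing alternatives were chosen before the data were examined. The text names the 12 highest and 12 lowest genes with a symbol that were at least 2-fold different and kept their sign under normexp and quantile normalization, up to 4 members of each list with the largest ratio either way, up to 5 genes per direction with the largest bound, and a fixed panel of 15 genes from Hmox1 to Mpst. Provisional identifiers did not count as symbols. Some list members that this rule selects are not reported here. Any other gene named was chosen after its values were seen.

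The spot error of a ratio comes from the spread of repeat spots at similar signal, in signal bins that were refined once after the first bins hid the larger spread of dim spots. Counts from single spot pairs were added after the ratios were seen. On simulated data with that spot noise (13673 genes), the rule of size called 3, 29, 50 and 50 of 50 genes changed by 1.5-, 2-, 3- and 4-fold, and 13 of 13473 unchanged genes. Of 100 random lists of 20 genes, 2 fell outside the 2.5 to 97.5 percentile range, and 100 of 100 such lists raised by 0.3 were found. Shorter lists were not simulated, so this does not cover the intestinal, metal response and immune lists, with 5, 6 and 7 measured members. The simulated noise was normal and held no outlier spots. The 13 is therefore too low as a count of false calls on these arrays. Rates from real spot pairs give 31.9 higher and 32.4 lower genes among 11827 read by 1 spot.

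The alternatives were scaling to the median of probes above background, quantile normalization, loess (span 0.3), spike-in scaling, normexp with an offset of 50 on the mean and background signals, the deposited table, no filter on dim probes, a stricter filter, the median over a gene's probes, and a rule of size of 1.5- or 3-fold. Tools were R 4.3.3 with limma 3.58.1 for normexp, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.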

Results

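Gene expression was measured in IEC6 cells, a non-transformed epithelial line from rat small intestine, after 60 min with sodium trisulfide (Na2S3), an inorganic polysulfide, or with water as the control. The comparison asks which transcripts differ after this exposure, as the series title and design text state. The sample label and the design text give the dose as 100 µM, whereas the treatment protocol in the labels gives 100 mM, so the dose is stated here as the labels' 100 µM with that conflict open. Total RNA of each group was hybridised to 1 Agilent single-colour (Cy3) array. There is 1 array per group and there are no replicates, so no difference below has a replicate check, no p-value is given across genes, and "higher" and "lower" describe these arrays. Of 45598 probes, 22560 (49.5%) were well above background on the control array and 22349 (49.0%) on the Na2S3 array. Across probes above background on both arrays, the log2 signals had a Pearson r of 0.993, computed over probes, which are not independent replicates.

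Acute transcription-factor and stress genes were among the genes that stood highest in the Na2S3 array. Atf3, a stress-induced transcription factor, had 26.9-fold the control signal (log2 ratio 4.75). Trib3, a pseudokinase gene that ATF4 induces, had 23.3-fold (4.54), and Fosl1, an AP-1 subunit gene, had 21.3-fold (4.41). With normexp background correction these log2 ratios were smaller, at 4.15 for Atf3, 3.54 for Trib3 and 3.04 for Fosl1. Vegfa, an angiogenic growth factor gene, had 8.87-fold and Ptgs2, the inducible cyclooxygenase gene, had 6.41-fold. Of 13062 genes measured on both arrays, 123 were at least 2-fold higher in the Na2S3 array and 81 were at least 2-fold lower, while 12229 (93.6%) lay within 1.5-fold. Members of the gene lists fixed beforehand made up 44 of the 123 higher genes and 2 of the 81 lower genes. Those lists hold only a small part of the 13062 genes, and several cover genes that stress or signals induce. They therefore say little about the lower genes.

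The rest of the 12 genes with the highest ratios had log2 ratios of 2.55 to 3.88. Akr1d1, which encodes a steroid reductase, had a log2 ratio of 3.88, Sesn2, a sestrin gene that restrains mTORC1 signalling, 3.21, and Nr4a1, an orphan nuclear receptor gene, 3.18. Chac1, whose product degrades glutathione, stood at 2.93, Hcls1 at 2.91, Iapp at 2.59 and Osgin1 at 2.55. Apart from Atf3, Nr4a1, Vegfa and Ptgs2, the 12 highest genes were each read by 1 spot per array. The error estimated from repeat spots at similar signal was 0.10 for Atf3, 0.13 for Trib3, 0.18 for Fosl1, 0.07 for Nr4a1 and 0.36 for Iapp, on the log2 scale. The Atf3 probe lay on chromosome 13 at 107191582 to 107191614, the Trib3 probe on chromosome 3 at 142664936 to 142664995, and the Fosl1 probe on chromosome 1 at 208099035 to 208099094, in the rn4 coordinates of the files. With normexp, Akr1d1 and Sesn2 both stood at 2.37, Nr4a1 at 1.64, Osgin1 at 1.61, Hcls1 at 1.36 and Iapp at 1.09.

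**Figure D1:**
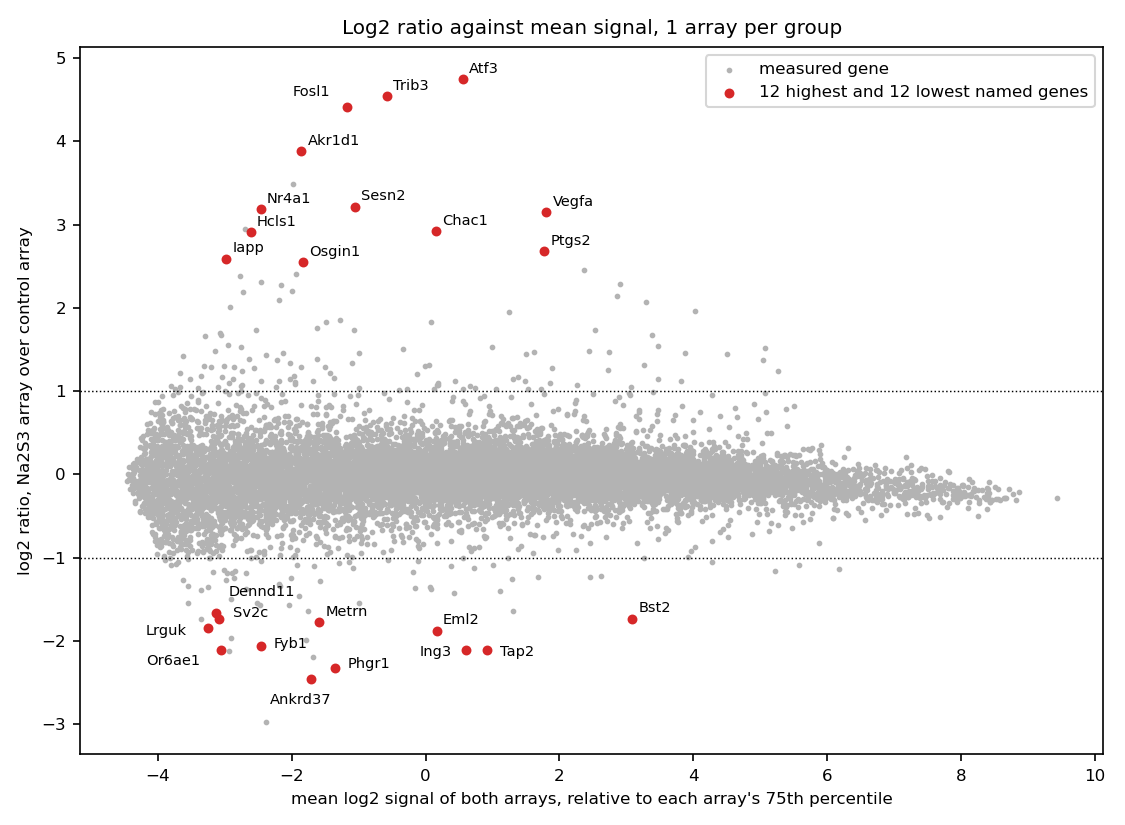
Each point is 1 of 13062 measured genes, with the mean log2 signal of both arrays relative to each array's 75th percentile on the horizontal axis and the log2 ratio of the Na2S3 array over the control array on the vertical axis; dotted lines mark 2-fold. Red points are the 12 highest and 12 lowest genes with a symbol that the naming rule selected, from 4.75 for Atf3 to -2.46 for Ankrd37.

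Immediate early genes, which signals switch on without new protein synthesis, were higher as a group. Of 33 measured members, 16 were at least 2-fold higher, 0 were at least 2-fold lower and 30 had a positive ratio. The list median was 0.97, above all 10000 random lists matched on signal (percentile 100). Beside Atf3, Fosl1 and Nr4a1, Myc had a log2 ratio of 2.46 and Egr1 one of 1.28. Fos, measured by 1 probe, had 0.38. Arc was well above background in the Na2S3 array alone and was at least 2.92-fold higher there.

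Targets of ATF4, the transcription factor of the amino acid and integrated stress response, were also higher as a group. All 21 measured members had a positive log2 ratio and 9 were at least 2-fold higher, with a median of 0.83 (percentile 100). Trib3 (4.54, and 3.54 with normexp), Sesn2 (3.21, and 2.37 with normexp), Chac1 (2.93) and Ddit4, an mTORC1 inhibitor gene (1.74), led the list. Cth, which encodes the cysteine-forming enzyme cystathionine gamma-lyase, was not well above background on either array. The endoplasmic reticulum chaperones and degradation factors of the unfolded protein response had 0 of 18 members past 2-fold, a median of -0.0054 and a mean of 0.05, which differ in sign (percentile 81.6). Herpud1 had the largest ratio of that list at 0.96 and passed 2-fold under quantile normalization, loess (1.04), spike-in scaling and in the deposited table, while Calr had 0.27, Pdia4 -0.23 and Dnajb9 -0.25.

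NRF2 target genes, which carry antioxidant response elements, split between a few members with high ratios and a majority close to 0. Of 28 measured members, 6 were at least 2-fold higher and 0 at least 2-fold lower, and the list median was 0.03 (percentile 98.4). Osgin1 (2.55), Srxn1, the sulfiredoxin gene (2.29), Slc7a11, the cystine transporter gene (2.09), Maff (1.95) and Hmox1, the heme oxygenase gene (1.02), passed 2-fold. With normexp Osgin1 stood at 1.61, Hmox1 at 0.95 and Slc7a11 at 1.08, and the list median was 0.11 to 0.12 under quantile normalization, loess and in the deposited table. Txnrd1 had 0.72 and Nqo1 0.11, and Gclm was not well above background on either array. Other antioxidant enzymes had 0 of 17 members past 2-fold and a median of -0.08 (percentile 42.9), with Prdx6 at 0.72 and Gpx4, Prdx3 and Gpx7 at -0.27, -0.27 and -0.24.

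Genes of sulfur metabolism had a median log2 ratio of -0.09 over 18 measured members (percentile 8.79). Cars1, a cysteinyl-tRNA synthetase gene, was 2.20-fold higher (1.14), and Got1, an aspartate aminotransferase gene, was 2.64-fold lower (-1.40). Cars2 had -0.35, Bhmt -0.39 and Mpst, which encodes a sulfurtransferase, -0.07. Cbs was not well above background on either array, and Csad was above background in the Na2S3 array alone, at least 1.25-fold higher. Metal response genes had 0 of 6 members past 2-fold and a median of -0.06 (percentile 61.4), with the metallothionein genes Mt1 at -0.22 and Mt2A at -0.38, Slc30a1 at -0.20 and Mtf1 at 0.23.

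Inflammatory targets of NF-kB had a median of 0.35 over 18 measured genes (percentile 100), with 4 at least 2-fold higher and 0 lower. Ptgs2 (2.68), Cxcl1, a neutrophil chemokine gene (1.48), Tnfaip3 (1.06) and Tnfaip2 (1.03) were those 4, of which Tnfaip3 (0.52) and Tnfaip2 (0.91) did not pass 2-fold with normexp, and Lif was above background in the Na2S3 array alone, at least 1.92-fold higher. Targets of TGF-beta and BMP signalling had a median of 0.48 over 16 genes (percentile 100), with 5 at least 2-fold higher, among them Junb (2.83-fold), Id1 (log2 ratio 1.12) and Snai2 (1.12). With normexp the list median was 0.28 and Snai2 stood at 0.63. Without Junb, which the immediate early list also holds, the median was 0.42 and 4 of 15 passed 2-fold. Of the 16 genes, 12 had a positive ratio and 4 a negative one. Beside Id1, the genes Id3, Id2 and Id4 had 0.11, 0.0060 and -0.28, so the Id genes were not higher together. Smad7 had 1.07 and Smad6 -0.15. Hypoxia genes had a median of 0.16 over 19 genes (percentile 99.8). Vegfa (3.15), whose probes gave 2.74 and 3.15, and Adm, the adrenomedullin gene (1.30), were at least 2-fold higher, Hk2 had 0.88, and Ankrd37 was lower (-2.46, and -1.65 with normexp).

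Heat shock genes under HSF1 did not share the high ratios of those groups. None of the 20 measured members passed 2-fold (0 higher, 0 lower), and the median was -0.13 (percentile 10.9). Hspa1a had -0.53, Hspa4 -0.65, Hsp90aa1 -0.31 and Hspa4l 0.64, although the probes of Hspa4l gave 0.64 and -0.16. Of 16 measured p53 targets, 2 were at least 2-fold higher, the polo-like kinase genes Plk3 (1.85) and Plk2 (1.07, and 0.95 with normexp). Cdkn1a, a cell cycle inhibitor gene, had 0.95 (1.03 as the median over its probes) and Sesn1 had -0.95. The p53 list's median of -0.09 (percentile 20.6) and its mean of 0.20 differ in sign, and with no filter on dim probes the median was 0.11.

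**Figure D2:**
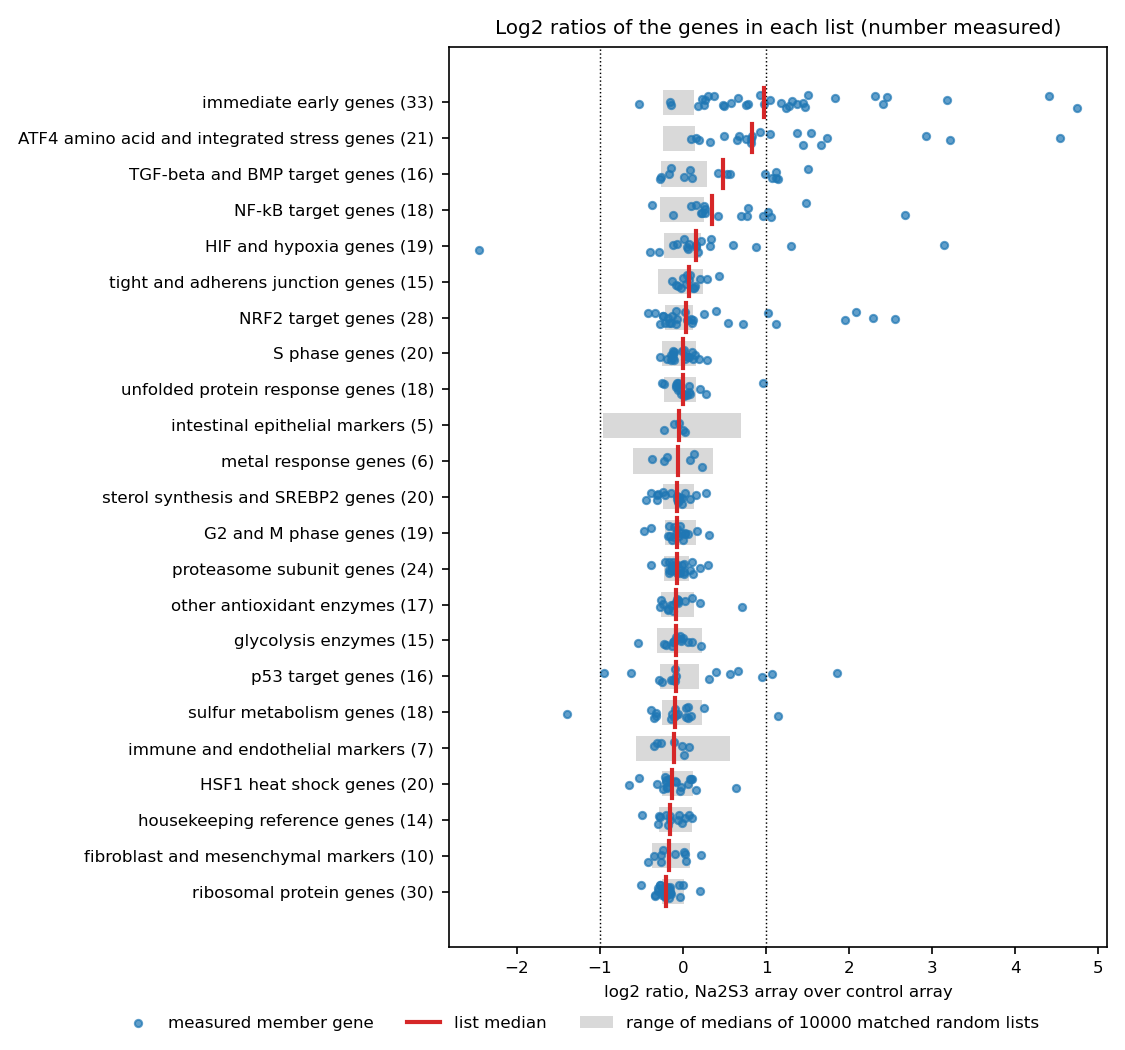
Each blue point is the log2 ratio (Na2S3 array over control array) of 1 measured member of a gene list, red lines are list medians, and grey bars span the medians of 10000 random lists matched on signal. The medians of the immediate early (0.97), ATF4 (0.83), TGF-beta and BMP (0.48) and NF-kB (0.35) lists lie above the grey bar, and dotted lines mark 2-fold.

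The measured epithelial identity genes showed no member past 2-fold, but most intestinal markers were not well above background on both arrays. Tight and adherens junction genes had a median of 0.07 over 15 genes (percentile 96.0), with Cldn1 at 0.44, Cldn12 at 0.29, Pard3 at 0.21 and Ocln at 0.15. The 3 probes of Pard3 ran from -0.21 to 0.21 and those of Ocln from -0.083 to 0.15, and Cldn1 stood at 0.15 with normexp. Intestinal epithelial markers had 5 measured members of 18 with a probe and a median of -0.05 (percentile 49.1), with Cdx1 at -0.23, Ascl2 at -0.11, Krt18 at -0.05 and Krt19 at 0.02. Control signals were 142 for Krt18, 183 for Ascl2 and 215 for Krt19, below that array's 75th percentile of 413, and 2086 for Cdx1. Of the fibroblast and mesenchymal markers, 10 were measured on both arrays, with a median of -0.17 (percentile 37.9), among them Col1a2 at -0.43, Thy1 at -0.35, S100a4 at -0.27 and Acta2 at -0.27. Immune and endothelial markers had 7 measured members and a median of -0.11 (percentile 25.9), with Vwf at -0.35, Ptprc at -0.32, Cd68 at -0.27 and Tek at -0.11. The fibroblast median was positive after loess, quantile normalization and in the deposited table.

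Cell cycle, metabolic and housekeeping lists had 0 members past 2-fold. S phase genes had a median of -0.000197 (20 genes, percentile 88.2), with Cdt1 at 0.28, Cdc6 at 0.19, Pcna at -0.19 and Ccne2 at -0.28, and G2 and M phase genes one of -0.07 (19 genes, percentile 20.7), with Aurka at -0.47 (0.05 at its other probe), Birc5 at -0.39, Ccnf at 0.32 and Ccnb2 at -0.18. Glycolysis enzymes stood at -0.08 (15 genes, percentile 46.1), with Hk1 at -0.54, Ldha at -0.23, Pkm at 0.22 (its 4 probes ran from -0.40 to 0.25) and Pgk1 at -0.20. Sterol synthesis genes stood at -0.07 (20 genes, percentile 45.6), with Fdft1 at -0.45, Stard4 at -0.32 and Hmgcs1 at -0.31. Proteasome subunit genes stood at -0.08 (24 genes, percentile 58.8), with Psma3 at -0.39, Psmd11 at 0.31 (-0.16 at its other probe), Psma6 at -0.22 and Psmc6 at 0.20. Ribosomal protein genes stood at -0.20 (30 genes, percentile 7.44), with Rpl18 at -0.51, Rps18 at -0.33, Rplp1 at -0.33 and Rpl32 at -0.30. Housekeeping reference genes stood at -0.16 (14 genes, percentile 17.5), with Rpl13a at -0.30, Ppia at -0.29 and B2m at -0.27. Random lists matched on signal averaged -0.15 for the ribosomal list and -0.11 for the housekeeping list. Much of these low medians was thus shared by other genes of similar signal. The metal response, unfolded protein response, S phase, sterol, proteasome and ribosomal medians were positive under loess, quantile normalization and in the deposited table, and so carry no settled direction.

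Genes lower in the Na2S3 array formed no group among the fixed lists, which hold only 2 of the 81. Ankrd37 had the lowest ratio among genes selected by the naming rule, 5.51-fold lower (-2.46), followed by Phgr1 (-2.33). With normexp background correction Ankrd37 stood at -1.65 and Phgr1 at -1.59. Tap2, a peptide transporter gene of antigen presentation, had -2.11 and -1.97 at its probes, and Bst2, which encodes the antiviral protein tetherin, had -1.73 with a spot error of 0.11. Or6ae1 (-2.11), Fyb1 (-2.07), Eml2 (-1.88), Lrguk (-1.85), Metrn (-1.78), Sv2c (-1.74) and Dennd11 (-1.66) made up the rest of the 12 lowest genes with Ing3, which had -2.11 at its brightest probe and 0.34 at the other. Apart from Tap2 and Bst2, the values of the 12 lowest genes, Ankrd37 and Phgr1 included, each rest on 1 spot per array. With normexp Or6ae1 stood at -1.06, Fyb1 at -1.18, Lrguk at -0.87, Sv2c at -0.88 and Dennd11 at -0.85.

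**Figure D3:**
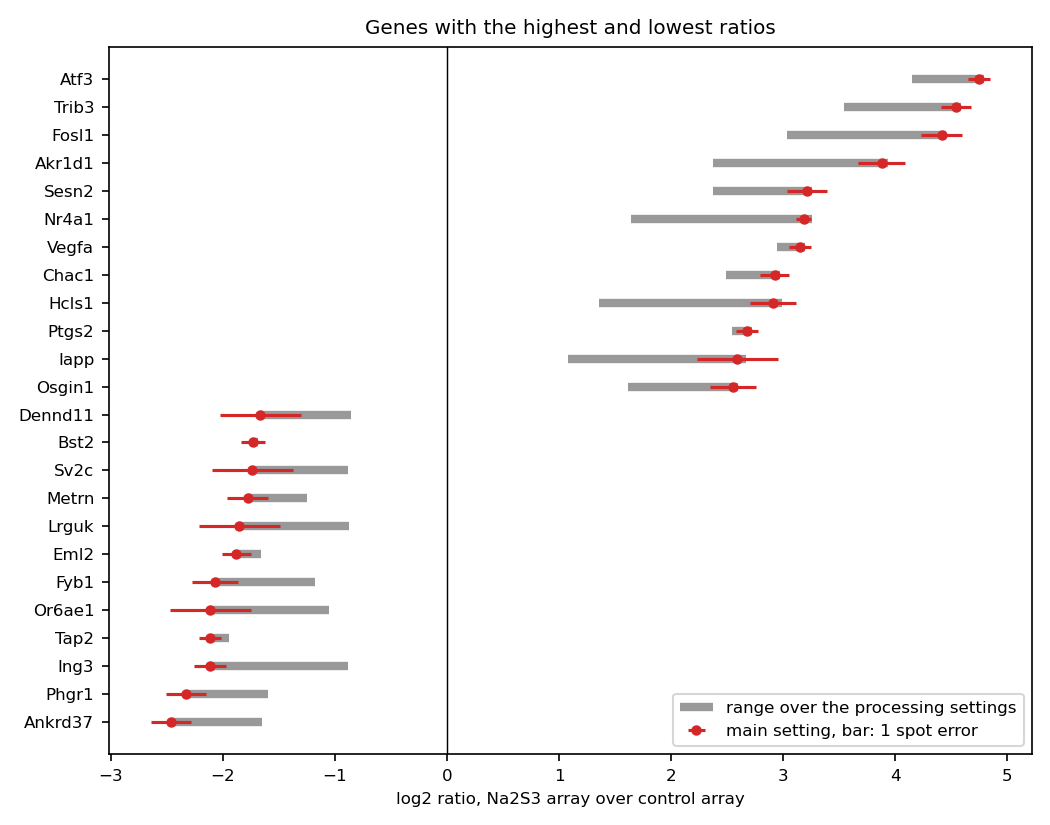
Red points are the log2 ratios (Na2S3 array over control array) of the 12 highest and 12 lowest genes that the naming rule selected, with bars of 1 estimated spot error, and grey bars span the values over all processing settings. The grey bar of Iapp runs from 1.09 to 2.67 and that of Ing3 from -2.11 to -0.89, while Bst2 stays between -1.73 and -1.69.

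A further set of genes was well above background on 1 array alone, with a bound of at least 2-fold: 109 in the Na2S3 array and 156 in the control array. With normexp these counts were 12 and 61. The largest bounds in the Na2S3 array were those of Psmb11 (at least 13.5-fold), Or5ac22 (6.67), Pnma1 (6.45), Jag2 (5.67) and Fam181b (5.65). In the control array they were those of Nuak1 (at least 22.4-fold), Golga6l9 (14.2), Fblim1 (13.9), Gpr31 (12.9) and Or7d11 (10.5). Probes spotted 10 times gave 0 such cases among 186 dim probes, against 401 of 23720 (1.69%) for probes spotted once. For the count of 0, an approximate one-sided 95% upper limit is 1.61%. Whether the 2 shares differ is undecided (Fisher's exact test, two-sided p = 0.0804).

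Measurement error was read from repeats within the arrays. The estimated spot error of a log2 ratio had a median of 0.14 and a maximum of 0.36, and different probes of the same gene differed with an SD of 0.24 (3181 genes). Of 26 genes past 2-fold with more than 1 measured probe, 15 had every probe at least 1.5-fold in the same direction and 4 had a probe of opposite sign. Single spot pairs of repeat probes that were themselves within 1.5-fold passed 2-fold higher in 7 and lower in 15 of 12875 pairs. At matched signal this rate gives 31.9 higher and 32.4 lower genes among the 11827 genes read by 1 spot, where 104 and 76 were found. Below a mean signal of 64 it gives 17.7 higher and 11.8 lower genes, where 22 and 27 were found. From 64 to 128 it gives 4.66 and 9.33, where 30 and 14 were found. From 128 to 256 it gives 8.61 and 4.30, where 13 and 11 were found. These expected counts below 256 are rough, since each rests on 1 to 3 spot pairs that passed 2-fold. Single spots could account for many calls below 256, least so for higher genes from 64 to 128. Of the 12 highest and 12 lowest genes read by 1 spot, Iapp, Or6ae1, Lrguk, Sv2c and Dennd11 lie below 64. Akr1d1, Hcls1, Osgin1 and Fyb1 lie from 64 to 128, and Fosl1, Sesn2, Ankrd37, Phgr1 and Metrn from 128 to 256. Normexp background correction left 61 genes higher and 31 lower, and with no filter on dim probes the counts were 1062 and 1545, so the share of higher genes went from 60.3% to 40.7%.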

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

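The tests on repeat spots, olfactory receptor genes and scaling were chosen after the results they bear on were seen, and Fisher's test was added to the comparison of probes spotted 10 times and once after its ratio was seen. The repeat-spot test was first run on probes spotted 2 times, where 1 of 7 spots left it undecided, and was then widened to all repeat probes.

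Probes that carry only an accession or transcript identifier, which the gene counts leave out, also held signals that differed between the arrays: of 4407 measured, 31 were at least 2-fold higher in the Na2S3 array and 70 were at least 2-fold lower.

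The 109 and 156 genes well above background on 1 array alone raise the question of single-spot defects. A brighter neighbouring spot is argued against by a difference of -0.11 in the median log2 signal of the brightest adjacent spot (bootstrap SD 0.10), and a switch of the whole set by Na2S3 is argued against by olfactory receptor genes, which made up 27 of 265 such genes and 1148 of 14164 dim genes, a ratio of shares of 1.26. Probes spotted more than once held 38 spots above background on 1 array alone. For 2 (5.26%, exact 95% confidence interval 0.644 to 17.7), at least 50% of the probe's other spots on that array were above background. Of the 38 spots, 31 were on probes spotted 10 times, and 0 of 186 dim probes spotted 10 times count in the set. A probe is dim when most of its spots are, so few other spots could be above background. The interval also treats spots of 1 probe as independent. This test therefore does not decide whether single spots were defective. The share of dim probes in the set was 0 times as large among probes spotted 10 times as among those spotted once. With 0 of 186 against 401 of 23720, this comparison also leaves the matter undecided (Fisher's exact test, two-sided p = 0.0804). Single genes of the set, such as Arc, remain open.

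The immediate early, ATF4 and NRF2 lists together had 31 of 82 measured members at least 2-fold higher and 0 at least 2-fold lower. Of the 7 higher members with more than 1 probe, 6 (85.7%, exact 95% confidence interval 42.1 to 99.6) had every probe at least 1.5-fold higher. That interval is too wide to decide alone, and members with 1 probe were not examined in this way. The 31 to 0 split argues against defects of single spots as the source of the whole set. The median of the 82 members lay between 0.70 and 0.75 over the scaling settings. Those settings moved the ratios of measured genes by a median of up to 0.043, so none could have turned the sign. The range shows only that the choice among these settings matters little here. With 1 sample per group, a difference between the samples other than Na2S3 cannot be told apart from the treatment. An effect of Na2S3 stays open as a hypothesis.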

How the results depend on the processing

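Every alternative here was planned, and no list median that stood outside 95% of random lists turned its sign under any of them. All of those medians were positive and no scaling alternative lowered the ratios at the median, so scaling could hardly have turned them. Counts of genes stayed within 1.5 times under every scaling alternative, the deposited table, the stricter filter and the median over probes. Normexp, whose offset is added to every signal and weighs most on dim ones, gave 61 higher, 31 lower, and 12 and 61 genes above background in the Na2S3 and control arrays alone. No filter gave 1062 higher and 1545 lower, since probes at background are then counted, and has no genes with a bound. A rule of 1.5-fold gave 387 higher, 446 lower, 171 and 290, and a rule of 3-fold gave 39, 20, 55 and 93. All 123 higher genes stayed past 2-fold under every scaling alternative and the deposited table, and 61 did under normexp. The scaling alternatives and the deposited table moved the ratios upward at the median, by up to 0.043, so they could hardly remove higher genes. The deposited table gave the same 141 higher and 67 lower genes by count as quantile normalization and is not a separate check. Of the 81 lower genes, 67 stayed under quantile normalization and in the deposited table, 70 under loess, 69 under spike-in scaling and 31 under normexp.

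Of 207 list medians under the alternatives, 54 moved by at least 1 SD of the medians of random lists, a yardstick chosen after the data were seen. With the bootstrap SD of the members' median, which was also tried, 41 did. The cause was not tested. Under the main scaling, ratios varied with signal. The medians of random lists matched on signal averaged -0.15 for the ribosomal list and -0.11 for the housekeeping list, against -0.02 for the NF-kB list. The list medians under quantile normalization, loess and the deposited table, in that order, were 0.11, 0.12 and 0.11 for the NRF2 list, -0.013, -0.0051 and -0.011 for the HSF1 list and 1.07, 1.08 and 1.07 for the immediate early list. In the same order they were 0.96, 0.95 and 0.95 for the ATF4 list, 0.056, 0.060 and 0.056 for the unfolded protein response list and -0.024, -0.0094 and -0.026 for the p53 list. The next were 0.38, 0.38 and 0.42 for the NF-kB list, -0.00045, -0.0049 and -0.00047 for the glycolysis list and 0.00033, 0.0049 and 0.0014 for the sterol list. Further ones were -0.019, -0.0079 and -0.019 for the other antioxidant list, 0.050, 0.052 and 0.050 for the fibroblast list and -0.017, -0.0036 and -0.018 for the G2 and M phase list. Then came 0.56, 0.54 and 0.56 for the TGF-beta and BMP list, 0.019, 0.028 and 0.018 for the proteasome list and 0.023, 0.022 and 0.020 for the ribosomal list. The last was -0.036, -0.022 and -0.034 for the housekeeping list. Under normexp they were 0.72 for immediate early, 0.27 for NF-kB and 0.28 for TGF-beta and BMP. Under no filter they were 0.11 for p53, 0.43 for NF-kB and -0.074 for fibroblast. Under spike-in scaling they were 0.074 for NRF2, -0.032 for proteasome and -0.16 for ribosomal. Of the values of named genes, 970 moved by less than the SD between probes of a gene (0.24) and 38 by more, 27 of these under normexp. Signal over background limits the dim genes most: the spot SD was 0.27 on the control array in the dimmest bin and 0.07 in the brightest.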

Other observations

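All tests in this part were chosen after the ratios were seen, so the genes here were named after their values were known, and each test leaves out the genes that the naming rule selected and those among the 45 highest and 30 lowest ratios, except the test of mitochondrial synthetases, which keeps all members. The criteria were revised after first values were seen: under the first ones the interferon-stimulated genes counted as not lower, and the zinc finger test was rewritten after its first form had come out opposite to its prediction. These lists were not recomputed under the processing alternatives.

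A mixed list of genes tied to ERK and EGF receptor signalling was looked at because several of its members stood among the highest ratios. It holds feedback inhibitors, such as the Dusp and Spry genes, and EGF-family ligands, and also genes that are neither, such as Etv5, an ETS transcription factor gene, and Epha2, a receptor tyrosine kinase gene. Of 19 measured members, 8 were at least 2-fold higher and 0 lower, among them Dusp5 (2.41), Phlda1 (2.27), Epha2 (1.96), Spry4 (1.76) and the ligand gene Areg (1.51). The 13 members left for the test had a median of 0.45, at percentile 100 of random lists matched on signal, but 3 of them, Dusp4, Dusp6 and Ier3, are also in the immediate early list. Without these 3 the median of the 10 others was 0.17, at percentile 97.34, so whether the list is higher beyond the immediate early genes is undecided. Etv5 (2.14-fold), Errfi1 (log2 ratio 0.86) and Hbegf (0.77) were among these 10, while Tgfa had -0.23. ERK activity itself was not measured.

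Cytosolic aminoacyl-tRNA synthetase genes, which charge tRNAs and of which several are ATF4 targets, were higher beside Cars1. The 19 members other than Cars1 had a median of 0.28, at percentile 100, with 17 positive and 0 past 2-fold. Sars1 had 0.89, Yars1 0.62 and Nars1 0.62, while Qars1 had -0.05. The 17 mitochondrial synthetase genes had a median of -0.02, at percentile 46.55. The 16 left without Cars2 had 0.02, at percentile 68.53. Both values argue against a shift shared by both compartments.

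Interferon-stimulated genes were looked at because Bst2 and Tap2 were lower. The 20 members left for the test had a median of -0.11, at percentile 6.34. Whether the group is lower in the Na2S3 array than other genes of similar signal is undecided. Zinc finger genes were looked at because 4 of them, Zfp39 (-1.57), Zfp296 (-1.57), Zbtb8a (-1.37) and Zfp879 (-1.27), were lower. The other 249 had a median of 0.02, at percentile 99.46, which argues against a group that is lower.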
